A study of Oryza sativa Japonica Group with 3 samples.

How the data were processed

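Messenger RNA levels were measured by sequencing in 3 libraries of whole seedlings of the rice cultivar Xindao-18 (Oryza sativa, Japonica group), whose seeds had been left untreated or implanted with a beam of low-energy nitrogen ions. Seedlings were grown on moist filter paper at 28 °C, with 12 h of light and 12 h of darkness, and sampled at 96 h. Per the labels' protocols, 50 buds of similar height were pooled for each of the control and 5 fluences. RNA of 2 such pools was then mixed, 10 µg from each, to make each irradiated sample. The low fluence library holds the pools given 1 and 2 in units of 1e+17 ions per square centimetre, and the high fluence library holds those given 6 and 8 in the same unit. The exponent is written without superscript in the labels and was read as 1e+17. Each group therefore has 1 library of pooled RNA, with no replicate, so no p-value is given and no difference can be set against a spread between replicates.

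The deposited values are FPKM (fragments per kilobase of transcript, scaled to the number of mapped fragments), 1 value per transcript, per the file headers. TopHat2 2.0.5 is named for read alignment in the submitters' processing notes. The program that assembled transcripts and estimated FPKM, the genome build, the annotation release and the use of strand are not given in the sources used here. The 3 files list the same 87523 transcripts in the same order. Of these, 66081 carry locus identifiers of the form LOC_Os, whose first digits give the chromosome and whose following number runs along it. A further 21257 carry the prefix CUFF, the form that the program Cufflinks gives to transcripts assembled from reads, and 185 belong to sequence not placed on a chromosome. Assembled transcripts have no coordinates or gene assignment in the files, and some may overlap an annotated locus and divide its reads. Nearness was read from the order of rows, which follows position only in part: 5582 of 66069 steps between annotated transcripts of a chromosome run backward, where stretches of a chromosome are interleaved.

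FPKM values were summed over the transcripts that share an identifier up to the transcript number. This gave 55759 annotated loci, 14179 assembled units and 185 unplaced models, 70123 features in all. The files do not pair identifiers with gene names. None of the 55759 locus identifiers matched the reference gene table (assembly ASM3414082v1) as written, and 1 matched a listed synonym once the LOC_ prefix was removed. The 35 gene lists that had been fixed as patterns on gene names and descriptions, and their comparison with 10000 random lists, could therefore not be run. No coordinates of that assembly are used.

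The following choices were made before the data were examined. Values were compared as deposited, as the log2 ratio of (FPKM + 1), which understates the change of low features. A feature counted as measured at a mean of at least 1 FPKM over the 3 libraries, and as differing at a ratio of at least 2 on that scale. A feature was set apart in the high fluence library if it differed the same way from both other libraries while these lay within 1.5-fold of each other. Features were to be named among those with a mean of at least 10 FPKM. Because names were not to be had, the 2 identifiers with the highest and the 2 with the lowest ratio are printed per comparison, and per direction for those set apart. Features chosen after their values were seen are described as such. Alternatives were median-of-ratios scaling, upper-quartile scaling, rescaling each library to an FPKM total of 1000000, no filter, a minimum mean of 5, pseudocounts of 0.1 and 5, and ratios of at least 3 and at least 1.5. Alternatives added after the data had been seen were each transcript on its own, rescaling each library to the FPKM total of the control, only features above 0 in all 3 libraries, and ratios centred on the median of 20 bins of mean expression.

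Total counts are not given with FPKM, so the depth of each library is unknown and no counting interval is given. Relative depth was estimated from annotated loci with a single transcript and values above 0 but under 0.2 FPKM in both libraries of a pair, where values are whole multiples of what 1 fragment is worth. Of 559 such loci, 82.8% had a low fluence to control ratio within 1% of the ratio of whole numbers up to 6 times a common step, against 10.4% for other steps. The corresponding shares were 75.5% of 983 loci for high fluence to control and 78.4% of 633 for high to low fluence. By this estimate the low fluence library had 0.499 times the depth of the control library, and the high fluence library 1.36 times.

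Unchanged libraries were simulated 100 times by giving each of the 3 libraries independent noise drawn from the low fluence to control differences of features of like expression, divided by the square root of their number per pair. All of that difference was thus treated as noise of equal size in each library. The simulation did not return its own input exactly: for low fluence against control it gave 3495 differing features on average against 3156 observed, and 270 against 186 among annotated loci with a mean of at least 10 FPKM. Its number of features differing at low fluence is therefore too high. The noise was matched on expression and not on feature class. At a mean of at least 10 FPKM, 9.39% of assembled units differed between low fluence and control, against 2.01% of annotated loci. The simulated numbers for annotated loci may thus rest on noise that is too large. The calling step was tested on simulated data of 30510 features for high fluence against control. It recovered 95.0% of 100 features changed 3-fold and 100.0% of 100 changed 6-fold, and called 2.93% of 11963 unchanged features with a mean of at least 10 FPKM. Such changes lie past the required ratio of 2, so high recovery follows largely from the rule. The share of unchanged features called depends on the simulated noise and is no error rate for the observed libraries. Analyses used Python 3.11.15 with NumPy 2.4.6 and pandas 2.3.3, and figures used matplotlib 3.10.9.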

Results

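Whole seedlings of rice were profiled by RNA sequencing at 96 h to compare untreated seed with seed implanted with nitrogen ions at low fluence, described in the labels as giving no significant damage, and at high fluence, described as giving significant damage. The biological effect in the labels refers to day 7 of culture, after the sampling, and the buds taken at each fluence were of similar height. Each group was represented by 1 library of pooled RNA. The libraries listed 48130 transcripts above 0 in the control, 45129 at low fluence and 50141 at high fluence, and 24804, 23652 and 25815 annotated loci, respectively. Total counts were not analysed here, and relative depth, estimated from the lowest values, ranked the libraries alike, at 0.499 times the control for low fluence and 1.36 times for high fluence. With a mean of at least 1 FPKM over the 3 libraries, 18934 annotated loci, 11569 assembled units without a gene assignment and 7 unplaced models were measured. All differences below are between single libraries, in FPKM as deposited, with folds on the scale of FPKM + 1.

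A pair of assembled transcripts dominated the sums of FPKM. CUFF.6362.1 was listed at 1690000 FPKM in the control, 2210000 at low fluence and 727454 at high fluence, and CUFF.11990.1 at 512355, 323062 and 149211. Together they made up 73.3% of the FPKM sum of the control, 76.3% at low fluence and 53.0% at high fluence. The highest annotated transcript, LOC_Os10g04800.1 on chromosome 10, stood at 48273 FPKM in the control, 46248 at low fluence and 28939 at high fluence. The sum over annotated transcripts was 607972 in the control, 587530 at low fluence and 528840 at high fluence. These features were chosen after their values were seen.

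The first comparison asked how seedlings given fluences without significant growth inhibition on day 7 differed from untreated ones. Annotated loci of the low fluence library lay close to the control: of 9265 with a mean of at least 10 FPKM, 86 were at least 2-fold higher and 100 at least 2-fold lower, 2.01% in all. Assembled units differed more often, with 146 higher and 126 lower of 2896, or 9.39%. The highest ratios belonged to the assembled units CUFF.8413, listed at 0 in the control, 212 FPKM at low fluence and 153 at high fluence, and CUFF.5596, listed at 0, 34.5 and 30.1. The lowest belonged to CUFF.11320, at 153 FPKM in the control and listed at 0 in both irradiated libraries, and to LOC_Os04g28370 on chromosome 4, at 133 FPKM in the control, listed at 0 at low fluence and at 28.9 at high fluence.

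Among annotated loci above 0 in all 3 libraries, the 2 highest and 2 lowest ratios at low fluence were picked after the values were seen. LOC_Os05g04720 on chromosome 5 stood at 0.180 FPKM in the control, 28.6 at low fluence and 12.2 at high fluence, 25.1-fold above control at low fluence. LOC_Os02g37250 on chromosome 2 stood at 4.38, 42.7 and 34.3 FPKM, 8.12-fold above control at low fluence. The assembled units listed beside LOC_Os02g37250 were also higher in both irradiated libraries, CUFF.5596 with the values above and CUFF.5577 at 67.5 FPKM in the control, 339 at low fluence and 115 at high fluence. LOC_Os04g51710 on chromosome 4 stood at 22.5, 0.00845 and 17.7 FPKM, 23.3-fold below control at low fluence, and the assembled unit listed beside it, CUFF.8933, at 2.11 FPKM in the control and 17.6 at low fluence. LOC_Os05g37200 on chromosome 5 stood at 23.8, 0.254 and 14.2 FPKM, 19.8-fold below control at low fluence, and the unit listed beside it, CUFF.9906, was listed at 0 in the control and at 14.6 FPKM at low fluence. Of the 100 lower annotated loci, 27 lay beside an assembled unit that differed at least 2-fold the other way and brought their difference under 1.5-fold once added.

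Over all 30510 measured features, 1524 were at least 2-fold higher and 1632 at least 2-fold lower at low fluence, 10.3% in all. Most of these had a mean under 10 FPKM, since 232 were higher and 226 lower among the 12163 features above that level. Of the 12163 features, 23 were listed at 0 in the control, 35 at low fluence and 12 at high fluence, an order that follows the estimated depth. The few annotated loci among them, 1 in the control, 5 at low fluence and 3 at high fluence, did not follow it fully. Whether depth gave these values of 0 was not tested.

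The second comparison set seedlings given fluences that inhibited growth by day 7 against untreated ones. Of the 9265 annotated loci with a mean of at least 10 FPKM, 220 were at least 2-fold higher and 482 at least 2-fold lower in the high fluence library, 7.58% in all against 2.01% at low fluence. The lower loci made up 68.7% of those differing. Among the 2109 annotated loci with a mean of at least 50 FPKM, 61 were higher and 144 lower, and their median log2 ratio was -0.26. Assembled units with a mean of at least 10 FPKM gave 204 higher and 255 lower. Lower loci outnumbered higher ones on each of the 12 chromosomes at a mean of at least 10 FPKM. Rescaling each library to an FPKM total of 1000000, which the 2 dominant assembled transcripts govern, shifted the median log2 ratio of high fluence to control by 0.63 and gave 1895 loci with a mean of at least 10 FPKM higher and 85 lower, a share of 4.29% lower. Rescaling to the total of the control library gave 2275 higher and 93 lower. Centring the ratios on the median of each expression bin gave 338 higher and 358 lower, a share of 51.4% lower.

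**Figure D1:**
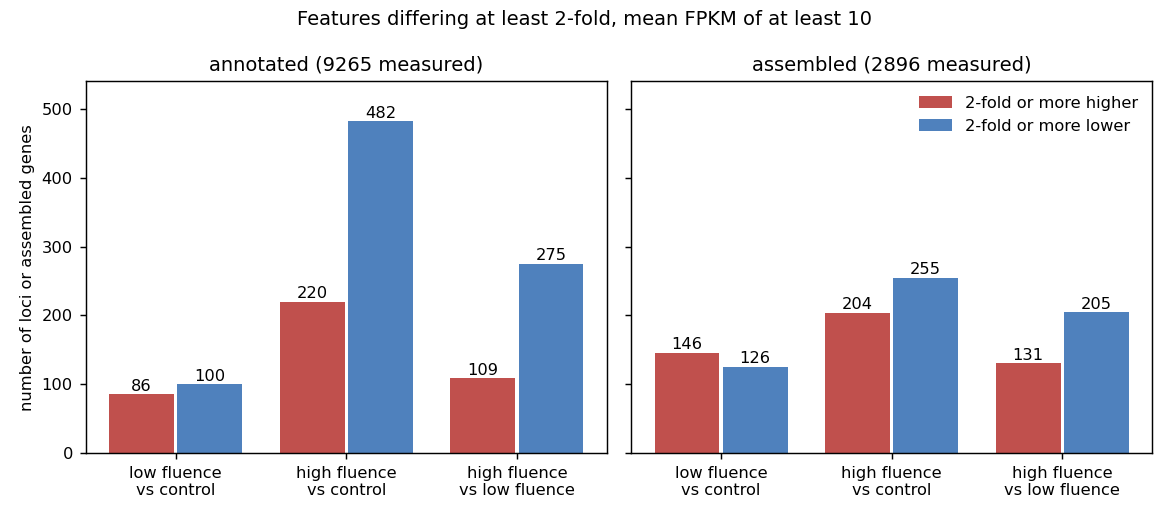
Number of annotated loci (left) and assembled units (right) at least 2-fold higher (red) or lower (blue) in each comparison of 2 libraries, among features with a mean of at least 10 FPKM. Among annotated loci the 482 lower at high fluence against control form the tallest bar, beside 100 lower at low fluence.

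The highest ratios at high fluence belonged to the assembled units CUFF.8170 and CUFF.4318, listed at 0 in both other libraries and at 19805 and 14826.5 FPKM at high fluence. The lowest belonged to CUFF.11320, described above, and LOC_Os08g42480 on chromosome 8, at 61.8 FPKM in the control and listed at 0 in both irradiated libraries. Among annotated loci above 0 in all 3 libraries, selected after the values were seen, LOC_Os03g47610 on chromosome 3 stood at 2.77 FPKM in the control, 5.80 at low fluence and 70.3 at high fluence, 18.9-fold above control. LOC_Os10g31420 on chromosome 10 stood at 2.28, 1.67 and 52.6 FPKM, 16.4-fold above control. LOC_Os03g39610 on chromosome 3, at 242 FPKM in the control and 309 at low fluence, stood at 3.18 at high fluence, 58.0-fold below control. LOC_Os09g17740 on chromosome 9, at 198 and 250 FPKM, stood at 3.23 at high fluence, 47.0-fold below control.

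**Figure D2:**
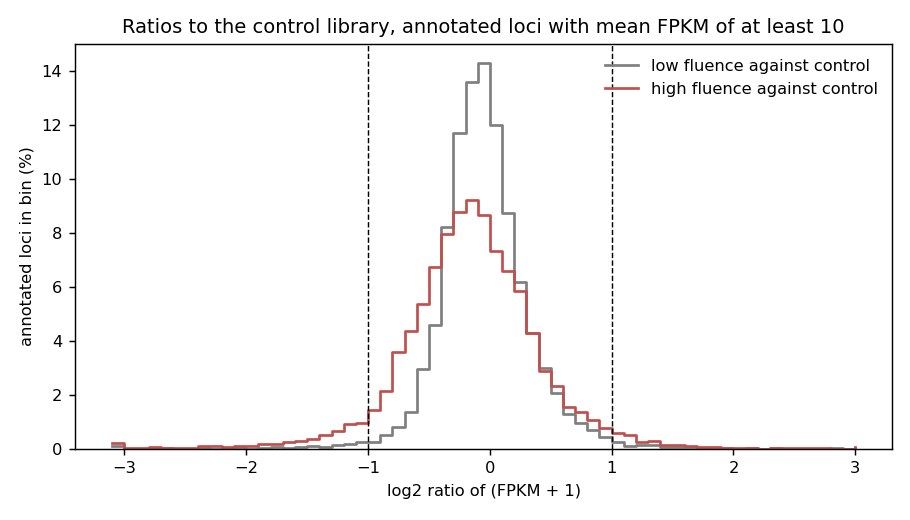
Share of annotated loci with a mean of at least 10 FPKM (vertical axis, percent) by log2 ratio of (FPKM + 1) to the control library (horizontal axis, in steps of 0.1), for the low fluence (grey) and high fluence (red) libraries, with dashed lines at a ratio of 2 either way and more extreme loci gathered in the end steps. The high fluence distribution is the wider, with a spread (scaled median absolute deviation) of 0.45 against 0.29, and a longer lower side.

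Several neighbouring loci differed together at high fluence. Of 5 runs of at least 4 neighbouring measured loci (locus numbers at most 30 apart) that differed the same way from control, 2 were higher and 3 lower, and they were singled out after their values were seen. On chromosome 10, the 4 loci from LOC_Os10g31420 to LOC_Os10g31490 were higher by a median of 10.1-fold, led in level by LOC_Os10g31460 at 18.1 FPKM in the control, 31.1 at low fluence and 217 at high fluence. None of these 4 differed at least 2-fold between low fluence and control. On chromosome 11, the 5 loci from LOC_Os11g47550 to LOC_Os11g47600 were higher by a median of 4.74-fold, with 2 of them listed at 0 in a library. On chromosome 10 as well, the 4 loci from LOC_Os10g40510 to LOC_Os10g40550 were lower by a median of 4.01-fold. LOC_Os10g40530 stood at 221 FPKM in the control, 116 at low fluence and 57.2 at high fluence. The run from LOC_Os03g52370 to LOC_Os03g52410 on chromosome 3 was lower by a median of 2.10-fold over 5 loci, of which LOC_Os03g52380 lay beside the assembled unit CUFF.7579, at 0.0121 FPKM in the control, 21.6 at low fluence and 13.1 at high fluence. The run from LOC_Os04g28360 to LOC_Os04g28420 on chromosome 4 was lower by a median of 4.37-fold over 4 loci, 2 of them listed at 0 in a library. Neighbouring loci can be near-identical copies that share reads, and the handling of such reads is not given in the sources used here.

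**Figure D3:**
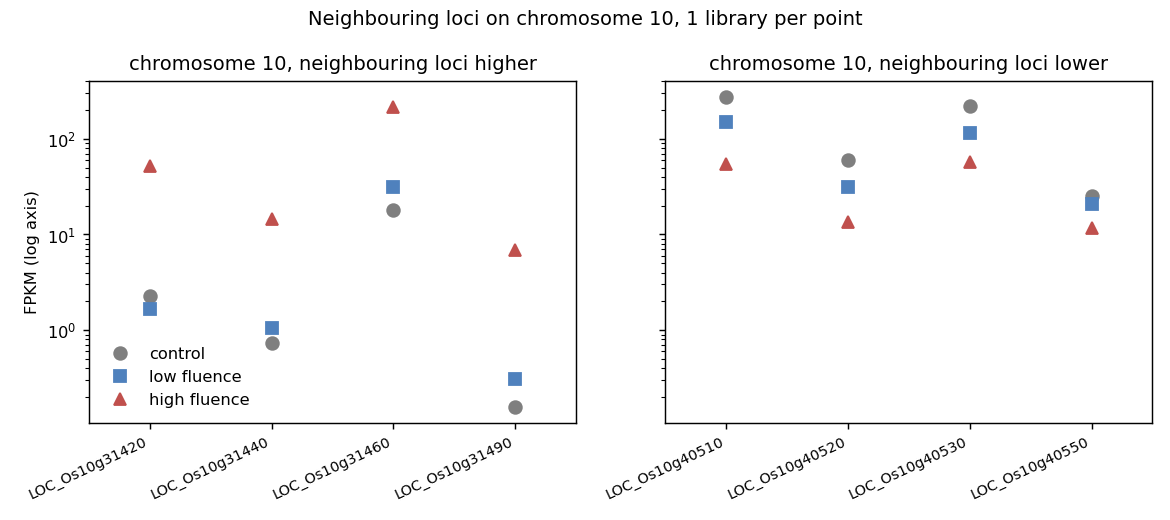
FPKM (log axis) of neighbouring loci in 2 runs on chromosome 10, with 1 point per library (grey circles control, blue squares low fluence, red triangles high fluence). In the run on the left the high fluence library lies above both others at each locus, up to 217 FPKM, and in the run on the right it lies below both, with low fluence in between.

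Over all 30510 measured features, 2039 were at least 2-fold higher and 2141 at least 2-fold lower at high fluence, 13.7% in all. Median-of-ratios scaling turned this to 2187 higher and 1993 lower, and upper-quartile scaling to 2236 and 1957. The assembled units leaned the other way from the annotated loci at this lower level, with 1239 higher and 941 lower against 800 higher and 1198 lower. Rescaling gave 5870 features higher and 489 lower at a total of 1000000, and 9333 and 804 at the total of the control.

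The third comparison set the fluences that inhibited growth by day 7 against those that did not. Of annotated loci with a mean of at least 10 FPKM, 109 were at least 2-fold higher and 275 at least 2-fold lower at high than at low fluence. Over all measured features the counts were 1804 higher and 1757 lower. Rescaling turned that split into 7295 higher and 335 lower at a total of 1000000, and into 11626 and 643 at the total of the control. CUFF.8170 and CUFF.4318 again had the highest ratios. The lowest belonged to LOC_Os07g40580 on chromosome 7, at 7.30 FPKM in the control, 243 at low fluence and listed at 0 at high fluence, and to LOC_Os03g39610, 74.3-fold lower at high than at low fluence. The values of LOC_Os07g40580 were mirrored by the assembled unit beside it in the files, CUFF.12300, at 252, 3.62 and 189 FPKM, so that their sum was 259 in the control, 246 at low fluence and 189 at high fluence.

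A set of 1146 features was set apart in the high fluence library, 480 higher and 666 lower than both other libraries. Among annotated loci with a mean of at least 10 FPKM, 39 were higher and 160 lower, 199 in all, or 28.3% of the 702 that differed between high fluence and control. Simulated unchanged libraries set apart 75.5 on average of 270 differing, or 27.9%. These shares cover both directions. By direction, 39 of the 220 higher loci and 160 of the 482 lower loci were set apart. The simulated share was not split by direction, and each simulated library had noise of equal size. The simulation therefore cannot show whether the larger observed number followed only from the larger number of differing loci. LOC_Os03g39610 and LOC_Os09g17740 led the lower features, and CUFF.8170 and CUFF.4318 the higher ones. LOC_Os09g17740 was 59.3-fold lower at high than at low fluence. Over all measured features the share was 27.4%, against 27.7% in the simulation. It also differed by direction, with 480 of 2039 higher and 666 of 2141 lower features set apart. Rescaling set 3473 features apart as higher and 93 as lower at a total of 1000000, and 5336 and 208 at the total of the control. Without the minimum mean, 843 were set apart as higher and 698 as lower, which turned the majority.

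Both irradiated libraries were also compared with the control for shared differences. A total of 757 features were at least 2-fold higher in both and 554 at least 2-fold lower in both. Independent lists of these sizes would share 102 and 115. Rescaling to the total of the control gave 915 and 361. Simulated unchanged libraries, which have a control in common, shared 1332 features on average against the 1311 observed, but from a longer list of differing features at low fluence, 3495 against 3156, and a shorter one at high fluence, 3498 against 4180. Among annotated loci with a mean of at least 10 FPKM, 51 were higher and 42 lower in both, 93 in all, against a simulated range of 59 to 110 from 270 differing loci on average in each comparison, where 186 and 702 were observed. The log2 ratios of the 2 irradiated libraries to control correlated across all measured features with r = 0.49, against a simulated mean of 0.50, and their covariance was 0.275, against a simulated mean of 0.234 and maximum of 0.244. Across annotated loci with a mean of at least 10 FPKM, r was 0.55 against a simulated maximum of 0.54, and the covariance was 0.131 against a simulated mean of 0.0943 and maximum of 0.106. Noise of equal size in libraries that share a control fixes the simulated r near 0.50, whereas the estimated depths were unequal. The simulated covariance is set by the noise given to the control, and how the observed noise divides between the libraries is unknown. Neither the observed r nor the observed covariances can therefore be judged as within or above chance. Genes are not independent replicates, and the single control library cannot be split, so part of this overlap may come from the shared control.

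The place of the low fluence library between the others was counted next. Among annotated loci with a mean of at least 10 FPKM that differed between high fluence and control, low fluence was intermediate for 177 of the 220 higher loci, or 80.5%, and for 404 of the 482 lower loci, or 83.8%. Simulated unchanged libraries gave 68.9% and 69.0% on average, and at most 76.6% and 77.7%. Among assembled units at the same level the shares were 65.2% of 204 higher and 71.4% of 255 lower, within the simulated ranges of 51.4% to 87.5% and 52.1% to 83.3%. The median log2 ratio to control of the higher annotated loci was 0.61 at low fluence and 1.24 at high fluence, where unchanged libraries that share a control gave 0.62 and 1.23 on average. That of the lower loci was -0.45 and -1.30, against simulated means of -0.63 and -1.23. In the simulation all called loci are noise, so its medians hold for no effect and not for the observed loci. Its libraries also had noise of equal size, whereas the estimated depths were unequal. The intermediate shares of annotated loci and of assembled units can therefore not be judged as within or above chance. Of the 5 runs of neighbouring loci, the lower run on chromosome 10 had a median log2 ratio to control of -0.89 at low fluence. The higher runs on chromosomes 10 and 11 had 0.21 and 0, and the lower runs on chromosomes 3 and 4 had -0.31 and -0.11.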

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

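The test of uneven depth, the stricter test of opposite neighbours, the tests of neighbours in single comparisons and the tests over 20 rows were chosen after the results were seen.

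Among annotated loci with a mean of at least 10 FPKM, 5 differed from control by at least 2-fold in opposite directions in the irradiated libraries, where simulated unchanged libraries gave 0.79 on average and at most 3, from 270 loci that differed at high fluence in place of 702. The difference between the directions was not tested, since each group has 1 library. LOC_Os01g52240 stood at 65.9 FPKM in the control, 143 at low fluence and 11.0 at high fluence, and LOC_Os12g11980 at 10.2, 55.2 and 1.49. LOC_Os08g04210 stood at 4.34, 1.52 and 41.8 FPKM. The remaining 2, LOC_Os07g40580, with the values given above, and LOC_Os07g08340, at 8.53, 2.49 and 25.1 FPKM, were each offset, in the comparison where they differed most, by an assembled unit listed beside them.

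Opposite values of an annotated locus and its neighbour in the files, as for LOC_Os07g40580, raise the question of reads divided between overlapping transcripts. Of 877 annotated loci with a mean of at least 10 FPKM that differed in any comparison, 128, or 14.6%, had an assembled unit within 2 rows whose addition brought the difference under 1.5-fold. Assembled units from random places did so for 8.12% on average, with 9.81% as the upper limit of the central 95% of draws, so the observed share was 1.80 times the random one, above chance but short of the 3-fold excess set beforehand. A stricter test was added because this result had been seen, since adding any abundant unit dilutes a difference, and it has less weight for that reason. It required the assembled unit itself to differ at least 2-fold the other way, and 54 loci, or 6.16%, met it, against 1.78% at random on average and an upper limit of 2.74%. Division of reads may account for loci of this kind.

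The comparisons differed in this respect. By the first criterion, 45.0% of the 100 loci lower at low fluence than in the control were offset in that comparison, against 12.5% at random on average, and 37.6% of the 109 loci higher at high than at low fluence, against 12.1%. Both exceed 3 times the random share, so division of reads may account for part of these loci. The share was 23.3% of the 86 loci higher at low fluence than in the control, above the random upper limit of 18.6%. It was short of 3 times the mean, which leaves it open by this criterion. Between high fluence and control it was 12.7% of the 220 higher and 6.85% of the 482 lower loci, within random upper limits of 13.2% and 8.51%. For loci lower at high than at low fluence it was 10.5%, within a limit of 10.9%. For these 3 sets, offset by units within 2 rows was not above chance by the first criterion. By the stricter one it was 4.73% of loci lower at high than at low fluence, above a random upper limit of 3.27%. Between high fluence and control it was 2.73% of the higher and 2.28% of the lower loci, within limits of 4.09% and 2.70%. For the 86 loci higher at low fluence than in the control it was 9.30%, above a limit of 5.81%.

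More features differed from control at high fluence than at low fluence, by a ratio that depended on level and threshold. It was 1.32 over all 30510 measured features, 2.53 at a mean of at least 10 FPKM and 3.77 for annotated loci at that level, but 1.09 at a required ratio of at least 3 and 1.09 for transcripts on their own. The explanations that follow were weighed at a mean of at least 10 or 50 FPKM only. Uneven depth would act the other way, adding differing features to the comparison with the shallower low fluence library. The test asked whether the excess vanished at high levels. At a mean of at least 50 FPKM the ratio of the counts was 3.96 (95% bootstrap interval over features 3.25 to 5.09). Noise that fades with level would itself raise this ratio, so the test does not show how depth affects its size. Division of reads would vanish in annotated loci with a single transcript and no assembled unit within 2 rows, but there the ratio was 5.76 (4.20 to 8.82). Rows follow position only in part, so an overlapping unit can lie farther off. Leaving out of the high fluence count alone the loci that any 1 assembled unit within 20 rows could offset, among annotated loci with a mean of at least 10 FPKM, gave 2.33 (2.00 to 2.74), and overlap beyond 20 rows was not tested. Over all features with a mean of at least 10 FPKM, subtracting the median ratio of each expression bin gave 2.52 (2.31 to 2.78), against 2.53 before. Removing shifts of the median with level thus left the ratio of the counts nearly unchanged. The subtraction does not alter the spread of the log2 ratios to control, which was 0.49 at high fluence and 0.31 at low fluence. Whether a spread that varies with level gave the excess was not tested. A difference between pools or library preparations cannot be told apart from fluence with 1 library per group, and the biological effect of fluence stays open on the same ground.

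Lower loci outnumbered higher ones at high fluence, and this may partly follow a trend of the ratios with expression level. After subtraction of the median of each expression bin the share of lower loci was 51.4% (95% bootstrap interval 47.9 to 55.1), against 68.7% before, but the subtraction itself draws the split towards equality, so the trend and a loss of particular transcripts cannot be told apart. Division of reads with units within 2 rows is argued against, since the share was 78.1% (71.6 to 83.7) in the 1778 loci with a single transcript and no such unit. With 166 of the 482 lower loci left out because a unit within 20 rows could offset them, and no higher locus left out, it was 59.0% (55.1 to 63.1), barely clear of the 55% set as the bound. The bootstrap takes loci as independent, but lower loci formed 93 neighbouring pairs against a shuffled mean of 49.6. The interval may thus be too narrow, and this test does not decide. Overlap beyond 20 rows was not tested.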

How the results depend on the processing

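Transcripts taken singly, rescaling to the control total, features above 0 in all 3 libraries and centring by expression bin were alternatives chosen after the data had been seen. No paired analysis was possible because each group has 1 library. Counts are given in the order low fluence against control, high fluence against control, high against low fluence, set apart at high fluence, and shared by both irradiated libraries, where the values as reported were 3156, 4180, 3561, 1146 and 1311.

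Under median-of-ratios scaling, upper-quartile scaling, no filter, centring, or only features above 0 in all 3 libraries, all 5 counts stayed within 1.5 times those reported. The majority direction was less steady: of 13 alternatives it turned in 3 for low fluence against control, 7 for high fluence against control, 5 for high against low fluence, 4 for features set apart and 1 for shared features. The last was a pseudocount of 5, with 125 higher and 164 lower. Features set apart turned under both rescalings, without a filter (843 higher, 698 lower) and at a ratio of at least 3 (206 and 193). Rescaling to an FPKM total of 1000000 gave 1436, 6359, 7630, 3566 and 565, and shifted the median log2 ratio by 0.63 for high fluence against control and by 0.73 for high against low fluence. It also shrinks all values, so that the pseudocount of 1 weighs more. Rescaling to the total of the control, which leaves the control values as deposited, gave 3135 and 1276 for low fluence against control and shared, within 1.5 times, but 10137, 12269 and 5544 for the others. The share of lower loci at high fluence, among annotated loci with a mean of at least 10 FPKM, turned from 68.7% to 4.29% and 3.93% under these rescalings. It was 63.2% under median-of-ratios and 61.5% under upper-quartile scaling.

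A minimum mean of 5 FPKM gave 977, 1908, 1332, 536 and 461, from 18177 features in place of 30510. A pseudocount of 5 gave 752, 1290, 951, 389 and 289. A pseudocount of 0.1 gave 4808 for low fluence against control and 2230 shared, with the other counts within 1.5 times. A ratio of at least 3 gave 1391, 1514, 1526, 399 and 459, and a ratio of at least 1.5 gave 7204, 9935, 8252, 3386 and 3629. Taking each transcript on its own gave 5799, 6318 and 6089 for the pairwise comparisons and 2370 shared, from 36232 transcripts, with the count set apart within 1.5 times. The minimum mean leaves fewer features to compare, the ratio moves the threshold itself, and a pseudocount sets the weight of low values. For transcripts on their own the cause was not tested. The gene lists fixed by name were not run under any setting, since names could not be matched. Total counts were not analysed here, so the limit that depth sets on single features is unknown.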

Other observations

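The tests of placement in this part were chosen after the values had been seen. Annotated loci that differed between high fluence and control were checked for lying side by side. Among 12651 pairs of measured loci that neighbour each other by locus number (a gap of at most 20), both members were at least 2-fold higher than control in 40 pairs and at least 2-fold lower in 93. Shuffling the calls within 20 bins of expression gave means of 21.7 and 49.6, with 31 and 63 as the upper limits of the central 95% of 10000 shuffles. At low fluence the pairs numbered 11 higher and 20 lower, with shuffled means of 11.3 and 14.9. Between high and low fluence, 21 higher pairs lay within the shuffles, whose mean was 15.7 and upper limit 24, and 40 lower pairs lay above theirs, whose mean was 25.6 and upper limit 35.0. A candidate explanation is a shared response of clustered gene copies, but reads shared between near-identical neighbours or between overlapping genes could give the same 93 pairs and were not separated from it. Median-of-ratios scaling gave 49 higher and 82 lower pairs, and rescaling to an FPKM total of 1000000 gave 368 and 10.

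Chromosome 10 held the highest share of differing loci at high fluence. Of its 473 annotated loci with a mean of at least 10 FPKM, 58 differed at least 2-fold from control, or 12.3%, while the other chromosomes ranged from 6.04% to 8.11%. In 12 of 10000 shuffles within expression bins some chromosome reached that share. Because differing loci lie in clusters, whole blocks of about 20 or about 50 neighbouring loci were also shuffled, and some chromosome reached 12.3% in 60 and 61 of 10000 shuffles, with 11.5% and 11.4% as the upper limits of the central 95%. Chance placement is argued against for these libraries, less strongly once clusters are kept whole, and clusters longer than these blocks were not tested.

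Within annotated loci of at least 2 transcripts and at least 10 FPKM in both libraries compared, the leading transcript differed for 219 of 3182 loci between low fluence and control and for 201 of 3122 between high fluence and control. The leading transcript's share moved by at least 50 percentage points in 53 and 26 of them. The comparison with the shallower low fluence library thus gave the larger number of such shifts, while the comparison with the high fluence library gave more loci that differed in total level.

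The 1 locus identifier that matched the reference gene table, LOC_Os01g19850, listed there with the synonym OsCCC2, stood at 0.361 FPKM in the control, 0.0804 at low fluence and 0.178 at high fluence, under the level at which features were compared.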
